A study of Mus musculus with 16 samples.

How the data were processed

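Genomic DNA from the tails of 8 C57BL/6 mice of 1 family was measured by array comparative genomic hybridisation, in which the DNA of an animal and that of a reference animal carry different dyes and compete for the same probes. The family comprised a sire, a dam and 6 progeny. Each was hybridised on 2 arrays against the DNA of 1 reference male of the same colony, once with the animal in Cy5 and the reference in Cy3 and once with the dyes exchanged. The arrays were a custom secondary-screening design. Per the series' design text, an earlier screen on a denser genome-wide array picked probes that deviated in this family, and the array used here surrounds those candidates with closely spaced probes. The content of the array was therefore chosen on these animals, and the counts of regions do not describe a random sample of the genome. The earlier screen and the quantitative PCR that the design text mentions were not used here.

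Per the file headers, the deposited scanner files were made with Agilent Feature Extraction 10.7.1.1 on genome build mm9 (NCBI37), with background subtraction, spatial detrending and a linear dye normalization and no lowess step. The files give, per the file headers, a processed intensity for each spot and dye and the log10 ratio of Cy5 over Cy3. The value table deposited with the series holds a log2 value per spot whose making is not given in the sources used here. Set against the scanner files, each of its 16 columns had a slope of 1 or -1 on the log2 ratio of the same array, which makes it log2 of reference over animal in every column, shifted by a small constant per array. The medians of its columns lay between -0.020 and 0.015. No column was left unused.

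Of 49692 features, 45768 were not controls and measured 41755 different probes. 41704 probes lay on autosomes, 48 on chromosome X and 3 on chromosome Y. Spots marked as non-uniform or as population outliers were left out, 92 to 127 per array. The log2 ratio of the processed signals was turned to animal over reference, repeated spots of a probe were averaged, each array was centred on its median, and the 2 orientations of an animal were averaged into 1 value per probe. No loess or quantile normalization was applied. The 2 arrays of an animal counted as 1 replicate, so values of a single animal have no biological replicate, and errors given as SD over probes measure technical spread.

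Probes at most 20 kb apart formed a block, and 1466 blocks held at least 3 probes (39558 probes in all, median 26 per block). Within blocks, intervals were called by a maximal-scoring procedure of the ADM-1 type. An interval needed a score of at least 6 (the sum of the values divided by the noise SD, a robust SD of the differences between neighbouring probes, and by the square root of the number of probes), at least 3 probes, an absolute mean log2 of at least 0.25, and the same sign and at least that size in each orientation. To count false calls, the same caller was run on the difference between the orientations of each animal divided by 2, in which copy number cancels, both as measured and after removing the mean dye effect of each probe. This difference is called the swap difference in what follows, and is meant as measured unless the removal is named. Intervals of the same sign that shared a probe were merged over animals. An animal carried a region where an interval of that sign called in it shared a probe with the region. Its mean over the whole region can then be near 0, as in progeny 4 (0.04) at a loss on chromosome 3 from 95374511. An animal lacked the region where no such interval was called and its absolute mean was under 0.15, and was otherwise uncertain. Shares of parental regions carried by progeny, and the transmission of the chromosome 4 gain, were tested against 50% with exact two-sided binomial tests, and the shares were given Clopper-Pearson intervals of 95%.

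Per-probe comparisons used limma (lmFit and eBayes, two-sided, Benjamini-Hochberg adjustment, adjusted p under 0.05) on 1 value per animal. Progeny were compared with parents, and the mean of all 8 animals with 0, the latter also with an absolute mean log2 of at least 0.25. That last test leaves out the spread of the reference animal. The animals are relatives and not independent draws. Regions were to be named in order of the number of carrying animals and then of size, up to 30, and the 10 probes with the greatest change in each direction per limma comparison. From that list the text names those with the greatest number of carriers and the greatest means and summarises the rest. The loss on chromosome 13 and the joining of 2 neighbouring regions on chromosome 4 into 1 tract were chosen after their values were seen.

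The caller was tested on simulated data made from the swap differences of 2 animals, drawn at random over probes with the mean dye effect removed, with 200 implanted regions per setting. With the noise of progeny 1 it found 100% of losses of 3 probes at a log2 of -1, 65.5% at -0.5 and 2.5% of gains at 0.35. With the noise of progeny 4 these shares were 100%, 100% and 87%. It made 0 to 4 false calls per simulation. The random draw leaves out noise shared by neighbouring probes, so these counts can be too low. In the swap differences themselves, with the mean dye effect removed, the caller made 40 calls in progeny 1 and 7 in progeny 4. In simulated animals with their own noise, limma found 196 of 200 probes changed by a log2 of 1 between progeny and parents, with 52 false calls among 41755 probes. For all animals against the reference it found 198 of 200 probes at 0.5, with 0 false calls.

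The arrays lay on 2 slides. The first held the sire, the dam and progeny 1 and 2, and the second progeny 3 to 6. The first slide was dimmer: its median signals over background ran from 110 to 240.5 units, against 639.5 to 1546 on the second. The number of arrays limits the precision. Alternatives fixed before the data were examined covered centring, background correction, the value table, filters on dim and flagged spots, each threshold of the caller, single orientations, leaving out each animal, and the slide as a block. Normexp was run on median signals because the files hold no mean signals. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, matplotlib 3.10.9, R 4.3.3 and limma 3.58.1 were used.

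Regions are given by their mm9 positions. Gene names were not assigned, because the files pair no probe with a gene and an annotation of that build was not used here. The planned test of gene lists, the correction for GC content and the filter on probes with several genomic matches were for that reason not run.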

Results

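Array comparative genomic hybridisation was used to look for DNA copy number changes in 1 mouse family of an experiment on continuous low dose-rate gamma irradiation of males, at 0.05 mGy per day for 400 days. A sire, a dam and their 6 progeny were each compared with the same reference male by a pair of dye-swapped arrays, 16 arrays in all. The sources differ on whether the sire of this family was itself irradiated, and no unexposed family was analysed here, so no value below measures an effect of radiation. The noise of the dye-swap mean, as an SD between neighbouring probes, was 0.112 to 0.157 on the log2 scale in the sire, the dam and progeny 1 and 2, which shared the first slide, and 0.055 to 0.070 in progeny 3 to 6 on the second. All positions are in mm9.

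The 48 probes on chromosome X checked the direction of the ratios, since the reference was male. The X mean minus the autosomal mean was 0.78 in the dam and -0.03 in the sire. In progeny 4, 5 and 6 it was 0.74, 0.70 and 0.74, and in progeny 1, 2 and 3 it was 0.01, 0.00 and -0.01. The SD over X probes was between 0.06 and 0.23 in each animal. In the dam the X mean was 0.68 with the animal in Cy5 and 0.86 with the animal in Cy3. A change from 1 copy to 2 corresponds to a log2 ratio of 1, so the arrays recorded less than the full ratio.

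**Figure D1:**
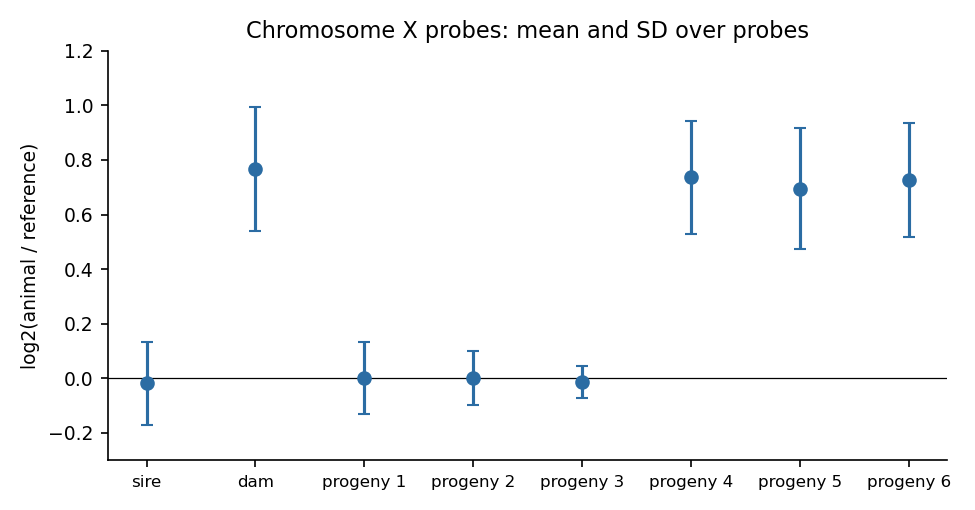
Mean log2 ratio of the chromosome X probes in each animal, with bars for the SD over probes (48 probes per animal). The dam and progeny 4 to 6 lie between 0.70 and 0.77, and the sire and progeny 1 to 3 lie near 0.

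Which copy number changes of the parents recurred in the progeny was asked by merging the intervals called in the 8 animals. The longest was a gain on chromosome 4 from 101123171 to 101271085, a tract of 147915 bp tiled by 602 probes. Its mean log2 ratio was 0.34 ± 0.22 (SD over probes) in the sire, 0.38 ± 0.23 in progeny 2, 0.35 ± 0.18 in progeny 3, 0.34 ± 0.17 in progeny 4 and 0.35 ± 0.17 in progeny 5. The dam, progeny 1 and progeny 6 had means of 0.00, 0.00 and 0.01. The 5 carriers had between 571 and 597 probes above 0. Both slides held carriers and non-carriers, and both orientations gave means of at least 0.30 in every carrier. 3 copies against 2 correspond to a log2 ratio of 0.58. The gain was thus present in 1 parent and in 4 of 6 progeny, with an exact two-sided binomial p of 0.688 against 50%. With 6 progeny only 0 or 6 carriers could give a p under 0.05, so this says little about transmission. With a required absolute mean of 0.4 the tract was not called in any animal, and with normexp background correction it was not called in the sire. Where only the mean of the orientations had to pass, an interval in it was also called in progeny 6.

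**Figure D2:**
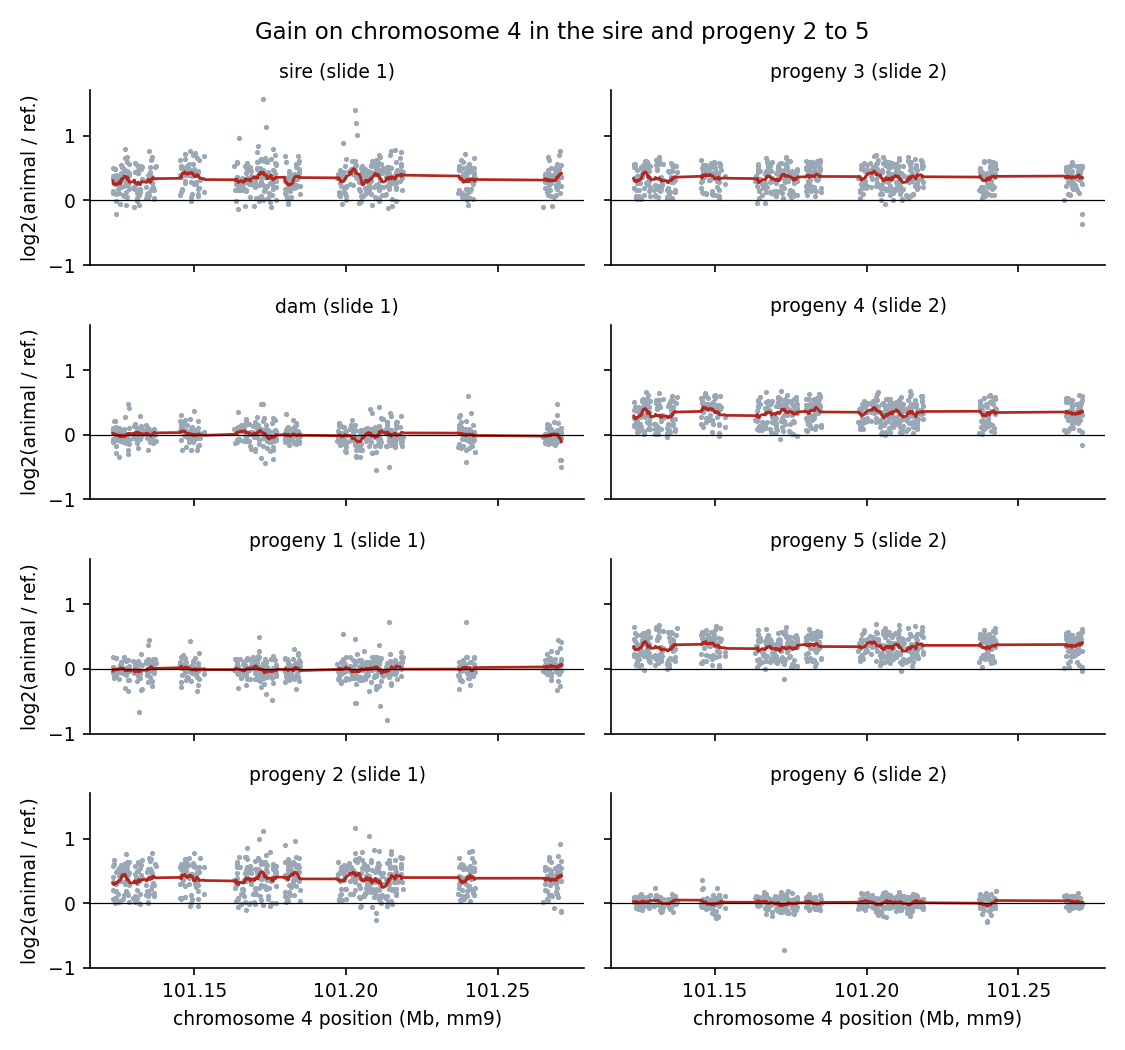
Log2 ratio of each probe against its position (Mb) on chromosome 4 in the 8 animals, with a running mean over 25 probes in red; the slide of each animal is given. The running mean lies near 0.35 along the whole tract in the sire and progeny 2 to 5 and near 0 in the dam, progeny 1 and progeny 6.

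A second group of regions was low in the dam and in progeny 4, 5 and 6. These 4 animals, and none of the others, carried 34 regions on 14 chromosomes. All 34 were losses, with carrier means from -1.63 to -0.23 and a median of 4.5 probes. The largest lay on chromosome 3 from 25416456 to 25447093, where 85 probes had a mean of -1.57 ± 0.70 (SD over probes) in the dam, -1.66 ± 0.69 in progeny 4, -1.64 ± 0.70 in progeny 5 and -1.66 ± 0.70 in progeny 6. In the sire and progeny 1, 2 and 3 the mean of this region was between -0.01 and 0.01. Single probes in it reached -3.43 in the dam. On chromosome 5 from 126318470 to 126322932, 13 probes had means between -1.30 and -1.22 in the same 4 animals and between -0.05 and 0.00 in the others. There the probes were uneven: the dam had a median of -0.24 and a lowest probe of -5.73. Shorter losses with the same carriers lay on chromosome 7 from 18816858 to 18817241 (dam -1.37), on chromosome 4 from 3892507 to 3892637 (dam -0.90), on chromosome 3 from 132549293 to 132549728 (dam -0.73), on chromosome 10 from 102877834 to 102878075 (dam -0.78) and on chromosome 6 from 104241190 to 104241514 (dam -0.72). The last 4 of these held 3 to 5 probes. In them the dam's median was between -0.16 and -0.05 and its SD over probes between 1.27 and 1.53, so each mean rested largely on 1 probe. The animals that carried these losses were the ones with the raised chromosome X ratio.

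**Figure D3:**
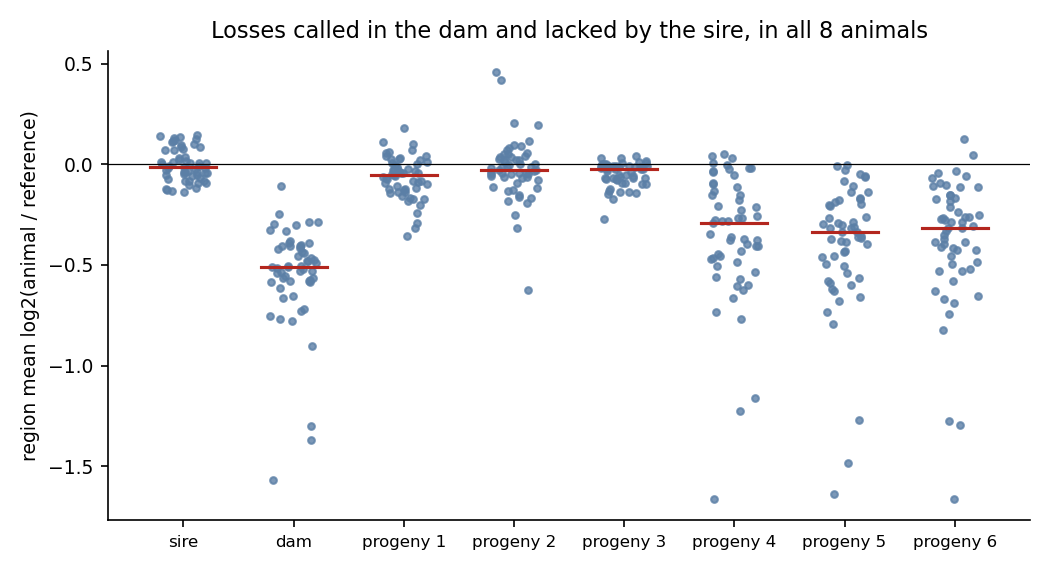
Mean log2 ratio of each of the 55 losses called in the dam and lacked by the sire, in all 8 animals; each point is a region and the red bar is the median over regions. The medians are -0.51 in the dam and -0.29, -0.34 and -0.32 in progeny 4, 5 and 6, against -0.05, -0.03 and -0.02 in progeny 1, 2 and 3.

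3 regions were low in all 8 animals. They lay on chromosome 5 from 93827988 to 93828109 (3 probes, means from -0.91 to -0.58), on chromosome 14 from 77752585 to 77752801 (4 probes, -0.72 to -0.32) and on chromosome 17 from 43384643 to 43385053 (4 probes, -0.56 to -0.33). Losses on chromosome 15 from 12670761, chromosome 12 from 107492889 and chromosome 18 from 50911385 were called in 7 animals each, and the remaining animal was also negative, at -0.27, -0.37 and -0.21. The chromosome 18 loss was uneven over its 5 probes. Its median was -0.11 to -0.09 in progeny 1, 3, 4 and 5, and -0.31 to -0.27 in the sire, the dam and progeny 6. It holds probe A_67_P08997810, which had a mean of -1.15 over the 8 animals. Because 1 reference served all arrays, a ratio shared by every animal cannot be assigned to the animals rather than to the reference.

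In all, the calls merged into 345 regions, 234 losses and 111 gains. Of these, 300 spanned 3 to 5 probes and 207 were carried by 1 animal. Both parents carried 17 regions that some animal did not carry. The sire and progeny shared 10, and 45 were called in the sire alone. The dam and progeny shared 63, of which 61 were losses, and 38 were called in the dam alone. The largest class, 114 losses and 20 gains, was carried by progeny while the state of at least 1 parent was uncertain. The remaining 35 were carried by progeny and lacked by both parents. Among regions called in the sire and not in the dam, progeny carried 16 of 238 settled cases, a share of 6.72% (95% Clopper-Pearson interval 3.89% to 10.69%). The 2 parts of the chromosome 4 tract made up 8 of the 16, and with the tract counted once the share was 5.17% (12 of 232). For regions called in the dam and not in the sire the share was 36.1% (181 of 501, 31.9% to 40.5%). Where the other parent had to lack the region, the shares were 10.3% for the sire (9 of 87, or 5 of 81 with the tract counted once) and 35.0% for the dam (119 of 340). Under the first rule the dam's losses were at 44.4% and the dam's gains at 2.04%. The 34 regions of the dam and progeny 4, 5 and 6 made up 102 of the dam's 181 carried cases and 90 of the 119. These animals are also the ones with the raised chromosome X ratio, so these cases need not be inherited losses. Exact two-sided binomial tests against 50% gave p = 1.47e-47 for the sire, 5.49e-10 for the dam and 0.0283 for the dam's losses under the first rule. They do not measure transmission, because false calls in a parent lower the shares. The sire had 75 calls against 105 in the swap difference, or 59 in it with the mean dye effect removed. Cases from the same animals are not independent, so the intervals are also too narrow.

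The comparison of the parents gave 82 regions carried by 1 parent and lacked by the other. The dam carried 55 losses and 10 gains of these, and the sire 14 gains and 3 losses. Of the 55 losses, 30 were carried by exactly progeny 4, 5 and 6 among the progeny. Those animals share the dam's raised chromosome X ratio. The 30 losses therefore cannot be told apart from a difference that follows that ratio. The greatest difference, sire minus dam, was 1.55 at the chromosome 3 loss. The smallest was 0.03, at a loss called in part of a region on chromosome 6 from 46165643 (dam -0.11, sire -0.07). The sire's gain on chromosome 4 differed from the dam by 0.34 over the 546 probes of its longer part. Among the regions that the dam lacked, the sire's highest gains spanned 3 probes each and lay on chromosome 1 from 26599053 (0.94 in the sire, 0.10 in the dam) and on chromosome 10 from 129513151 (0.77 and -0.01), which no progeny carried. In the former, probe A_67_P00031200 had a mean of 1.03 over both parents, so the contrast did not hold alike at each probe. There is 1 animal per parent, and the difference has no replicate check. With a required score of 8 the count fell to 34.

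Changes present in progeny and absent from both parents are candidates for germ-line changes. 1 such region stood out by length. On chromosome 13 from 65971874 to 66027149, all 34 probes of a block spanning 55276 bp were below 0 in progeny 1, with a mean of -0.45 ± 0.19 (SD over probes). The sire had -0.05 ± 0.11, the dam -0.07 ± 0.09, and progeny 2 to 6 lay between -0.04 and 0.00. Progeny 1 had the lowest of the 8 values at 33 of the 34 probes. Its mean was -0.54 with the animal in Cy5 and -0.36 with the animal in Cy3. The block holds no probe outside the loss, so the array gives no end point for it, and a change from 2 copies to 1 corresponds to -1. It was called under 15 of 16 alternative settings of the caller, the exception being a required absolute mean of 0.4. Progeny 1 lay on the noisier slide.

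**Figure D4:**
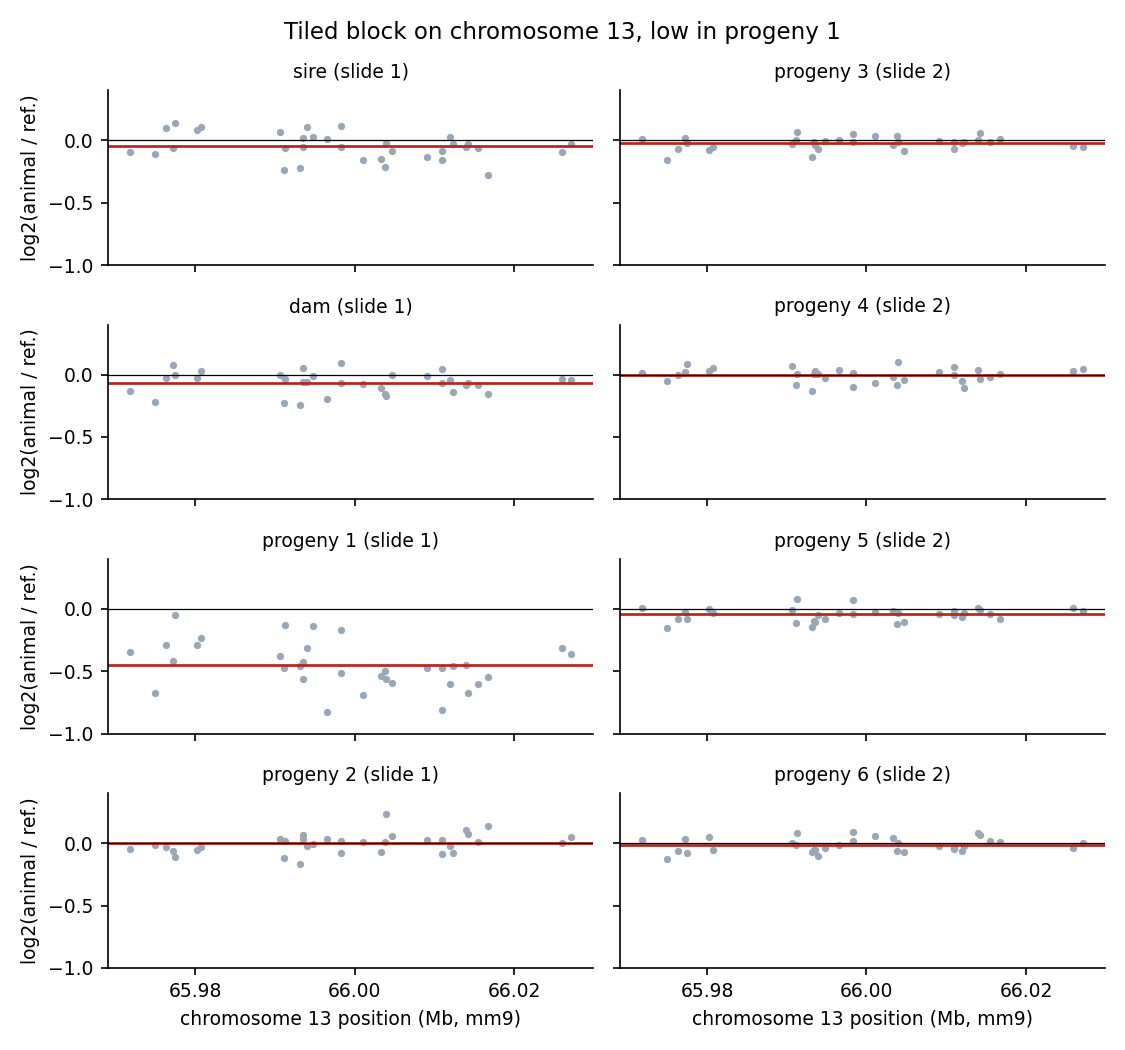
Log2 ratio of the 34 probes of a block on chromosome 13 against position (Mb) in the 8 animals; the red line is the mean over probes and the black line is 0. Progeny 1 has a mean of -0.45, and the means of the other 7 animals lie between -0.07 and 0.00.

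Of the 35 regions carried by progeny and lacked by both parents, 26 were losses and 9 gains, and 28 were carried by 1 animal. All but 2 spanned 3 to 6 probes. The other long one was a loss on chromosome 11 from 3095484 to 3100205 (16 probes), called in progeny 1 at -0.27. There progeny 2 had -0.30 without a call, and the dam had -0.12. Regions on chromosome 12 from 85752071 and from 118957261 were carried by exactly progeny 4, 5 and 6. The dam was not called there, at -0.11 and -0.10. Those on chromosomes 2 (from 8834092), 4 (from 135592225) and 16 (from 97498114) were carried by progeny 4 and 5, with progeny 6 at -0.27, -0.23 and -0.32. These progeny shared the losses of the dam, so these regions need not be new. Regions on chromosomes 9 (from 76671164) and 6 (from 60888093) had other pairs of carriers. Of the 35, progeny 1 carried 13 and progeny 2 carried 13, against 1, 6, 7 and 4 in progeny 3, 4, 5 and 6. The same rules applied to the swap difference gave 23 such regions, against 35. With the mean dye effect removed the counts were 40 in the swap difference and 53 in the ratios. Most of the regions were thus matched in number by noise, and which of them are real was not settled by the counts. Without progeny 1 it was 23 and without progeny 2 it was 22. With a required absolute mean of 0.4 it was 7.

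Per animal, 683 intervals were called, 533 losses and 150 gains. The dam had 89 losses and 34 gains, together the most of any animal. Progeny 5 had 114 intervals, progeny 4 had 99, progeny 6 had 91, progeny 2 had 80, the sire had 75, progeny 1 had 62 and progeny 3 had 39. Gains made up 62 of the sire's calls and 2 of those of progeny 6. The swap difference gave 105 calls in the sire, 99 in progeny 1, 86 in progeny 2 and 39 in progeny 3, as many as or more than the calls themselves. In the dam and progeny 4, 5 and 6 it gave 66, 23, 19 and 17. As measured, the swap difference keeps the mean dye effect of each probe, which cancels in the ratios. With that effect removed it gave 59, 40, 56 and 3 calls in the sire and progeny 1, 2 and 3. For the dam and progeny 4, 5 and 6 these counts were 47, 7, 4 and 3. In total it gave 454 calls as measured, against 683 in the ratios, and 219 with the mean dye effect removed, against 802. Of the 219, 202 were on the first slide and 17 on the second. Intervals of 8 or more probes numbered 12 in the sire, 8 in the dam and 2 to 5 in each of the progeny.

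**Figure D5:**
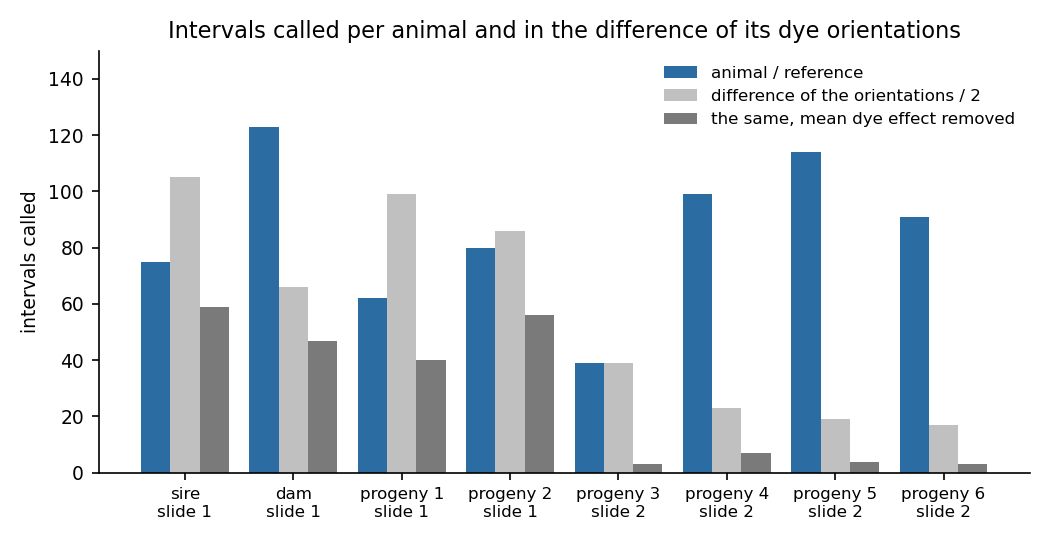
Number of intervals called in each animal (blue), in the difference of its dye orientations divided by 2 (light grey) and in the same after removing the mean dye effect of each probe (dark grey). Calls exceed both grey bars in the dam and in progeny 4, 5 and 6, and stay at or below the light grey bar in the sire and in progeny 1, 2 and 3. They exceed the dark grey bar in every animal.

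The orientations of an animal, both turned to animal over reference, correlated across probes at Pearson r = -0.32 in progeny 3, -0.23 in progeny 1, -0.19 in progeny 2, -0.08 in the sire, 0.02 in progeny 4, 0.03 in the dam, 0.06 in progeny 6 and 0.28 in progeny 5. Spearman's rho was negative in all 8 animals, from -0.53 to -0.06. After the mean dye effect of each probe was removed, Pearson r was 0.11 to 0.58 and Spearman's rho -0.11 to 0.30. Probes are not independent replicates. A negative correlation arises where the dye effect exceeds the copy number signal. The rule for calling a region asked for the same sign in both orientations, so the called regions say nothing on this point.

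Tested as a group against the reference, 229 of 41671 probes passed the threshold (limma, adjusted p under 0.05), 204 lower and 25 higher in the animals. The lowest was A_67_P14576908 on chromosome 7 from 6333281 (-1.19 ± 0.10 SE, n = 8, adjusted p = 0.000453). A_67_P08997810 on chromosome 18 from 50911528 followed at -1.15 ± 0.08 and A_67_P01616322 on chromosome 7 from 125624968 at -1.13 ± 0.09. Each was negative in 8 of 8 animals. The highest was A_67_P07959016 on chromosome 13 from 95707465 at 1.16 ± 0.10 (adjusted p = 0.000419), positive in 8 of 8 animals. The next, A_67_P00943909 and A_67_P00943841 at 0.44 each, lay in the longer part of the chromosome 4 tract, which held 22 of the 25 higher probes. That part was a gain in only 5 of the 8 animals, so these probes do not mark a ratio shared by all. A_67_P00943909 was positive in 7 of 8 animals. Of the probes named here, A_67_P14576908, A_67_P01616322 and A_67_P00943909 were not well above background on every array. They drop out where dim probes are left out. Only 8 blocks held 3 or more called probes of 1 sign. They included chromosome 4 from 46133336 to 46134418 (4 probes, -0.55 ± 0.06, SD over 8 animals) and chromosome 1 from 35437637 to 35437866 (3 probes, -0.46 ± 0.11). Without progeny 5 the count was 145, with 1 higher probe. On the first slide alone it was 1 and on the second 279.

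Between progeny and parents, 992 probes passed the threshold (limma, adjusted p under 0.05), 432 higher and 560 lower in the 6 progeny. At the probes with the greatest change the parents lay away from 0 and the progeny near it. A_67_P02950557 on chromosome 14 from 118440786 had a mean of -0.14 ± 0.27 (SD, n = 6) in progeny and 1.22 in the 2 parents, a difference of -1.36 ± 0.21 SE (adjusted p = 0.037). A_67_P04816709 on chromosome 3 from 5508677 differed by -1.14 ± 0.22 and A_67_P12550591 on chromosome 4 from 27054684 by -1.14 ± 0.15. Among the higher, A_67_P00078927 on chromosome 1 from 59843580 had 0.15 ± 0.12 in progeny and -0.72 in the parents, a difference of 0.88 ± 0.09 SE (adjusted p = 0.027). A_67_P17786876 on chromosome 12 from 33065593 and A_67_P04078930 on chromosome 1 from 42777266 differed by 0.85 each. The former had the opposite sign, -0.07, in the Cy3 orientation alone. Normexp background correction kept the sign of all these differences but made each much smaller. In the order given, they became -0.40, -0.31, -0.55, 0.21, 0.09 and 0.28. None of these probes was well above background in both dyes on every array. All of them drop out where dim probes are left out, so that setting does not test them. The count depended on single animals. It was 0 without progeny 3, 1 without progeny 5, 0 without progeny 6, 572 without progeny 4, 140 without the sire and 1810 without the dam. With the slide as a block it was 2472. Within the first slide, which holds both parents and 2 progeny, it was 0 (4517 probes at an unadjusted p under 0.05). Both fits gave the same differences, such as 0.98 at A_67_P00078927, since both parents lie on that slide. The block fit also drew its error from the less noisy second slide, so its higher count does not show a stronger difference. With array weights the count was 0 (6682 probes at an unadjusted p under 0.05).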

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

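The tests of this part were chosen after the results were seen, except the block means of progeny 1 and the regrouping of the animals, and the test of the slides was narrowed, after its values were seen, to losses that progeny 4 to 6 carried. Among 40 sets of values of the 6 progeny, 2 had an animal far from the other 5, and chance alone gives about 1 in 20, which is 2 of 40. The first of these was among the 40 because it had been picked for being low in progeny 1 alone, so its place here was fixed beforehand.

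The first was the chromosome 13 loss, with progeny 1 at -0.45 and the other 5 between -0.04 and 0.00. Noise of the first slide did not reach it: the highest score in the swap differences of that slide's 4 animals was 13.7, against 20 for the loss. A trend along the genome is argued against by the other blocks of at least 20 probes, whose lowest mean in progeny 1 was -0.18, and a few extreme probes by the 33 of 34 probes at which progeny 1 was the lowest animal. The lower parent's mean was -0.0662, the dam's, but the region was picked among those that both parents lacked, so this value tests nothing about a parent. When the loss arose, its size short of -1, repeated sequence in this block and a mixture of cells in the tail were not tested.

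The second was a region of 4 probes on chromosome 6 from 104785721, where progeny 1 had -0.42 and was not called while the other 5 lay between -0.28 and -0.23.

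The losses shared by the dam and progeny 4, 5 and 6 were weighed next. A difference between the slides is argued against: progeny 3, on the slide of progeny 4 to 6, lay above all 3 by at least 0.25 in 27 of the 32 losses that those animals and the dam carried and the sire lacked. Separately inherited autosomal variants are argued against as the whole account, since on 11 of 15 chromosomes every settled loss of the dam had the same carrying progeny, and since a dam lacking both copies on chromosome 3 would pass a loss to all 6 progeny, while progeny 1 to 3 lay near 0. In that region progeny 4, 5 and 6 had means of -1.66, -1.64 and -1.66, with the sire at -0.01. These lie below -1, the value for 1 copy in place of 2, which argues there against a loss received from the dam alone. Sequence with further copies on the Y chromosome remains open. The 3 progeny with the lowest ratio at the 3 Y probes had the 3 lowest means in 39 of the 55 losses, but they are progeny 4, 5 and 6, so the count restates the pattern and does not decide. The sex of the progeny is not in the labels. In the X and Y ratios progeny 4, 5 and 6 lay with the dam (Y means -1.57 to -1.37, dam -1.49), and progeny 1, 2 and 3 with the sire. The losses thus followed these ratios, and their sharing is not by itself evidence of inheritance from the dam. Only 3 Y probes were present, and the sequences were not examined.

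The 992 probes between progeny and parents were also weighed. Of the 28 ways to divide the 8 animals into 6 and 2, only 1, the labelled one, gave as many, and the highest of the others gave 2. Both parents lay on the dimmer slide, so the divisions are not interchangeable although the test was planned over all 28, and the 6 pairs within that slide are too few for a share under 0.05. Of these, the 5 others gave 2904 to 5314 probes at an unadjusted p under 0.05, against 10122 for the parents and at most 3083 for the 22 pairs with an animal of the second slide. Unequal noise of the animals was left open: with limma array weights the count was 0 (6682 probes at an unadjusted p under 0.05), but the median absolute difference of the 992 probes stayed at 0.31, while its median SE was 0.0555 before and 0.0702 after. What ended the calls was not tested further. All 992 were still at an unadjusted p under 0.05, but they had been picked for a low p on the same values. Simulated animals with these noise levels gave 52 false calls, far fewer than 992. Their noise was drawn at random over probes. The simulation therefore leaves out noise tied to particular probes or shared by the parents, and does not decide the question. A biological difference between parents and progeny stays untested.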

How the results depend on the processing

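Results given here that rest on the median of probes, the mean dye effect, a common noise level, array weights, 1 slide (except the first slide for progeny against parents), the exclusion of sex chromosome probes and the settings for the X ratio were chosen after seeing the data. Of the recomputed counts and values that answer a comparison, 81 stayed within 1.5 times or within their spread and 50 moved; the cause was not tested except where fewer animals or probes entered. The 683 calls became 338 with normexp, 390 without dim probes, 448 with a score of 8, 314 with 5 probes, 335 with a mean of 0.4, 424 with the median rule, 319 with the noise of the noisiest animal for all and 343 on slide 2 alone. In the same order, without the median rule, the 345 merged regions became 129, 150, 195, 169, 180, 180 and 149. The 35 regions of progeny alone became 13 without dim probes, 13 with a score of 8, 16 with 5 probes, 7 with a mean of 0.4, 80 with the mean of the orientations alone, 59 with the Cy5 orientation alone, 21 with the median rule, 53 with the mean dye effect removed and 6 with the noisiest animal's noise, and 22 to 34 with 1 progeny left out; without a parent they have no value. The 82 regions between the parents became 43 with normexp, 49 without dim probes, 34 with a score of 8 and 52 with 5 probes. The 992 probes between progeny and parents became 496 with normexp, 1564 without dim probes, 31 and 204 with the Cy5 and Cy3 orientations alone, 2472 with the slide as a block, 0 on slide 1 alone, 0 with array weights and 0 to 1810 with 1 animal left out. The 229 probes against the reference became 412 with no size limit, 3516 and 2560 with the Cy5 and Cy3 orientations alone, where the dye effect does not cancel, 1 on slide 1 alone, 833 with array weights and 145 to 220 with 1 animal left out. With normexp 129 of 252 were lower, against 204 of 229. The X ratio of the dam was 0.46 with normexp against 0.78. Probe A_67_P17786876 turned to -0.0724 in the Cy3 orientation alone. Under every setting of the signals the chromosome 4 gain of the sire lay between 0.25 and 0.36, the chromosome 13 loss of progeny 1 between -0.54 and -0.36 and the chromosome 3 loss of the dam between -1.59 and -1.27. Signal over background was not tested against calls; with the noise of progeny 1, on the dimmer slide, 65.5% of implanted losses of 3 probes at -0.5 were found, against 100% with that of progeny 4. The GC correction, the filter on repeated matches and the gene list test were not run. No paired analysis was possible because each animal is 1 sample of its group and the numbers pair none of them.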

Other observations

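The intervals listed here were chosen by length after the calls were seen, and no explanation was tested for any of them by itself. Intervals of 8 or more probes numbered 12 in the sire, all gains. They included those on chromosome 12 from 108353537 (0.60, 8 probes), chromosome 6 from 36555028 (0.55, 9 probes), chromosome 4 from 97623754 (0.52, 8 probes) and chromosome 15 from 92612430 (0.40, 10 probes). The sire and the dam both had gains on chromosome 3 from 109267820 (0.37 and 0.36, 10 probes each) and on chromosome 8 from 118286027 (0.42 and 0.45). All lay on the dimmer slide, where the swap difference gave 356 intervals (202 with the mean dye effect removed) and the ratios 340.

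Further losses of 8 or more probes were called in the dam on chromosome 8 from 60966496 (-0.40, 9 probes), chromosome 18 from 54140952 (-0.29, 9 probes) and chromosome 3 from 95374629 (-0.28, 12 probes). All of these belong to the 55 losses of the dam lacked by the sire that were weighed above. Progeny 5 had a loss on chromosome 13 from 77817425 to 77818639 (-0.50, 10 probes), which the dam, progeny 4 and progeny 6 also carried in part. It belongs to the 34 regions that these animals shared. A loss on chromosome 16 from 44425156 to 44426100 was called in progeny 4 (-0.33, 8 probes) and progeny 5 (-0.36, 8 probes).

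The 3 probes on chromosome Y had mean log2 ratios of -1.49 in the dam, -1.37 in progeny 4, -1.40 in progeny 5 and -1.57 in progeny 6, and of -0.06 to 0.00 in the sire and progeny 1 to 3. The lowest of the 3 was between -3.45 and -3.21 in the former animals, and the highest between -0.23 and -0.08.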
